A study of Mus musculus with 383 samples.

How the data were processed

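Single endothelial cells of the placental labyrinth, the layer in which fetal and maternal blood exchange nutrients and gases, were profiled by a full-length RNA protocol adapted from SMART-seq2.5. Each of the 383 samples was 1 cell, and the cells came from 4 litter-matched wildtype mouse placentas at E16.5 of gestation (96, 95, 96 and 96 cells). Cells are not replicates, so the placenta was the replicate throughout (n = 4). The p-values measure how far differences between groups of cells inside a placenta varied over the placentas of 1 litter. No 2 cells had identical values (383 distinct cells).

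The authors deposited a matrix of 29112 genes by 383 cells that holds estimated counts per gene, not normalized, of which 31.0% of the values above 0 were not whole numbers. The counting program is not given in the sources used here. Per the submitters' processing notes, bcl2fastq, Seurat and the mouse assembly GRCm39 were used, without versions or roles. The available reference annotation is of another build, so genes are named by the symbols of the matrix and no coordinates are printed. Of the listed genes, 9 were not in the matrix, Xist among them. The authors also deposited a table of cells with their own clusters and pseudotime, a score that orders cells along a trajectory. The cell names in that table matched no sample label, so it was summarised only as a whole and never joined to the matrix.

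Estimated counts were summed over the cells of a placenta and class, and each sum was rounded to whole numbers before testing. A sum needed at least 5 cells. Total counts per placenta ranged from 27295226 to 72692200, and totals per cell from 414 to 3486295. Reads carried no molecular identifiers that could be used here, so every interval and every limit from a count of 0 covers counting error alone. No doublet caller was run, because each library came from 1 deposited cell.

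2 ways of dividing the cells were used. For the arteriovenous axis, each cell received the mean standardised log2(CPM + 1), centred in its placenta, of 12 venous marker genes minus that of 12 arterial marker genes. Cells were ranked inside each placenta and divided into an arterial, a middle and a venous group of equal size. Such a group is a range of this score and no cell type, and 64 cells lay within 0.1 SD of a border. Genes of both marker lists set the axis and were left out of the genes tested on it. For zones, cells were clustered after centring in each placenta (2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 0.5), because the authors' clusters could not be tied to the samples. Only the marker lists were used to name clusters, and none received a name.

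Sums were compared with edgeR's quasi-likelihood test after TMM scaling and filterByExpr with the class as group. The model had the class and the placenta, the latter as a block because the classes of a placenta share an animal, and Benjamini-Hochberg adjustment at 0.05 covered all genes tested. The axis contrast was the venous against the arterial group (11700 genes tested), and each cluster was set against the mean of the others (11595 genes tested). Means are given as CPM of the summed counts with the SD over 4 placentas, or, where said, as the mean CPM per cell, and log2 fold changes with their standard error. Gene lists were tested with camera at a preset correlation of 0.01 on the voom values of limma, two-sided and adjusted over the lists. An estimated correlation and fry were the alternatives. A list needed 5 tested members, and 27 lists were fixed. On the axis 20 lists were tested, which left out the arterial and venous lists that define it and the immune, stromal, decidual, yolk sac and X-inactivation or Y-linked lists, which had too few members. On the clusters 23 lists were tested, without the immune, decidual, yolk sac and X-inactivation or Y-linked lists.

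The gene lists, designs, most alternatives and the rule for naming genes were fixed before the data were examined. That rule took, with 4 contrasts, the 5 largest rises and 5 largest falls per contrast among genes past the threshold that moved the same way in every placenta and reached 20 CPM on the higher side. It left out predicted genes, mitochondrially encoded genes, ribosomal proteins and pseudogenes. It added Dnmt1, Dnmt3a, Dnmt3b, Uhrf1, Tet1, Tet2, Tet3, Klf2, Klf4 and Nos3 at any value, and the 4 members of each list with the smallest p. Cell type shares carry exact binomial (Clopper-Pearson) 95% intervals, and a count of 0 is given with the simpler limit of 3 counts of the total.

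The alternatives were DESeq2 size factors, library size alone, no filter on low counts, the DESeq2 test, no placenta block, each placenta left out in turn, a quality filter on cells (1000 detected genes, at most 10% mitochondrial counts), no cycling cells (4 of 9 markers at 10 CPM), limma on mean CPM per cell, no cells of other types, 2 groups of equal size in place of 3, an axis from the odd-numbered or the even-numbered markers alone, and an axis after removing the trend with depth. Chosen after seeing the data were 3 restrictions of the cells, to the authors' range of detected genes, to cells with at least 200000 counts and to cells in which no pericyte or stroma marker reached 10 CPM, and clusters formed on one part of the genes and tested on the rest. The steps were tested on simulated sums in which 50 genes were changed at each of 4 sizes. On the axis, over 11722 genes, 4%, 34%, 48% and 62% of the genes changed by 1, 2, 3 and 5 on the log2 scale were recovered, with 1 false call among 75. For the clusters, over 11595 genes, these shares were 4%, 18%, 44% and 70%, with 4 false calls among 72.

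Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scanpy 1.11.5, scipy 1.17.1, python-igraph 0.11.9 and matplotlib 3.10.9.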

Results

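Gene expression was measured in 383 single endothelial cells from the labyrinth of 4 wildtype mouse placentas of 1 litter at E16.5 of gestation. Placentas 1 to 4 contributed 96, 95, 96 and 96 cells, with totals of 72692200, 70679765, 51084045 and 27295226 estimated counts. The median total per cell was 692943, 656581, 401536 and 193974, and the median number of detected genes was 4926.5, 4747, 4325.5 and 3943. The title of the series asks how zones of the placental vasculature are specified and names epigenetic mechanisms, so cells were compared along the vascular tree inside each placenta.

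The libraries carried endothelial transcripts and few transcripts of other placental cells. The 12 pan-endothelial genes, among them Pecam1, Cdh5 and Kdr, summed to 20848 ± 511 CPM (SD, n = 4). In 0 of 383 cells did the trophoblast, erythroid, immune, stromal, decidual or yolk sac list exceed the endothelial list, which allows a share of up to 0.783%. With all cells pooled, trophoblast markers summed to 143 CPM, pericyte and stromal markers to 95.01, immune markers to 18.98, erythroid markers to 12.6, decidual markers to 6.76 and yolk sac markers to 1.90. Trophoblast markers reached 348 CPM in placenta 2 against 29.1 to 51.1 in the others. At least 3 markers at 10 CPM were found in 7 cells for stroma, 6 for erythroid cells, 3 for trophoblast and 1 for immune cells.

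Y-linked genes separated the placentas. Ddx3y, a Y-linked RNA helicase, was detected in 56 of 95 cells of placenta 2 (58.9%, 95% exact binomial interval 48.4 to 68.9%) and in 54 of 96 cells of placenta 3 (56.3%, 45.7 to 66.4%). It had a count in 0 of 96 cells of placenta 1 and 0 of 96 of placenta 4, which allows up to 3.13% (3 of 96) in each. Eif2s3y gave the same division, with 28 and 20 cells in placentas 2 and 3 and 0 in the others. Kdm5d and Uty, which have close X-linked relatives, were also counted in placentas 1 and 4 (Kdm5d mean 6.25 and 1.44 CPM against 46.3 and 36.9), and their assignment is uncertain.

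Cells were ranked inside each placenta by venous minus arterial marker genes and divided into an arterial, a middle and a venous group of equal size. Between the arterial and venous groups 54 genes differed. Cxcl12, a chemokine made by arterial endothelium, averaged 1092 ± 581 CPM in the arterial group and 20.3 ± 17.3 in the venous group (SD, n = 4), a log2 change of -6.00 ± 0.74 (SE). Vegfa, the main vascular growth factor, went from 256 ± 92.1 to 8.80 ± 4.51 CPM (-4.91 ± 0.52). Ptgs1, a cyclooxygenase of prostaglandin synthesis, rose from 27.4 ± 9.84 to 266 ± 81.3 CPM (3.30 ± 0.38), and Tgfbi, a matrix protein induced by TGF-beta, from 65.0 ± 23.4 to 344 ± 87.5 CPM (2.44 ± 0.22). Col15a1, a basement membrane collagen, had 2 counts in the arterial groups and 7380 in the venous groups, a ratio of 3094 with a counting interval of 856 to 25557. Of the 7380 counts 3846 came from placenta 2. The interval treats reads as independent and covers neither amplified copies nor the spread between cells or placentas. Col15a1 had a count in 9.14% of all cells, so a small part of the cells carried it. Elastin, Eln, had a count in 18.0% of all cells. It averaged 2020 ± 1668 CPM in the arterial group, 4.94 ± 7.43 in the middle and 70.7 ± 75.1 in the venous group. Without the 85 cells in which a pericyte or stroma marker reached 10 CPM its log2 change went from -4.98 to -1.34 ± 1.098 (edgeR adjusted p = 0.864).

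Of 11700 genes tested, 54 passed the threshold, with 19 higher in the venous group and 35 higher in the arterial group. All 54 moved the same way in 4 of 4 placentas, and for 51 the middle group lay between the ends, the exceptions being Cd300lg, Cdkn1a and Eln. The median change was 3.14-fold among genes higher at the venous end and 2.96-fold among those higher at the arterial end. By edgeR's quasi-likelihood test the adjusted p was 0.00597 for Cxcl12, 0.00311 for Vegfa, 0.00412 for Ptgs1, 0.00148 for Tgfbi and Col15a1, and 0.0181 for Eln. The other genes with the largest changes were Prcp, a peptidase that cleaves angiotensin (2.90 ± 0.45, adjusted p = 0.0227), and Lbp, the lipopolysaccharide-binding protein (2.13 ± 0.32, adjusted p = 0.0196), at the venous end, and Ntn4, a netrin (-3.52 ± 0.59, adjusted p = 0.0313), and Arhgap8 (-3.41 ± 0.39, adjusted p = 0.00412) at the arterial end. The count fell to 29, 8, 17 and 11 genes without placenta 1, 2, 3 and 4 in turn, of which 23, 8, 16 and 10 were among the 54. Of the 24 named genes past the threshold, Tgfbi, Ace and Col18a1 kept their calls whichever placenta was left out, and DESeq2 called 537 genes, all 54 included. The median total per cell was 434373 counts in the arterial, 392265 in the middle and 512448 in the venous group.

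**Figure D1:**
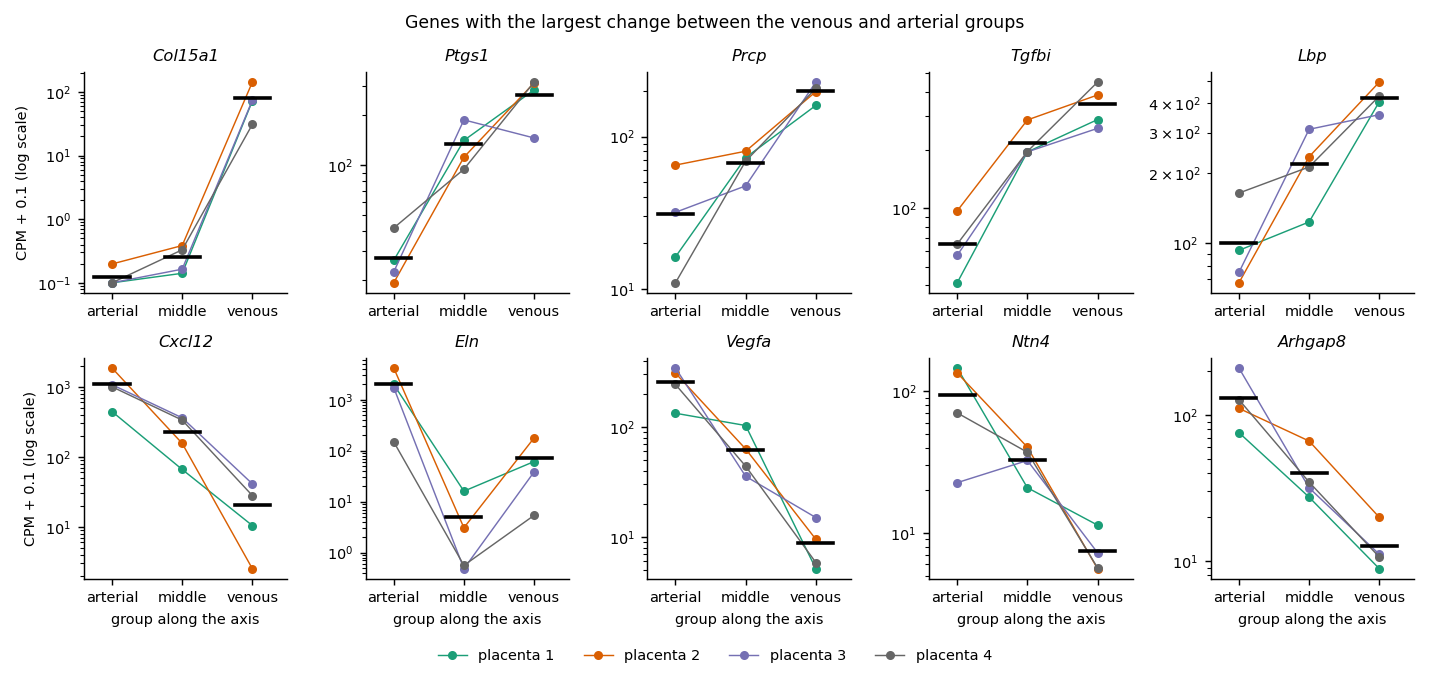
Levels of the genes with the largest changes along the arteriovenous axis, in CPM plus 0.1 on a log axis, by group of the cells. Points are the 4 placentas and black bars their mean; Cxcl12 goes from a mean of 1092 CPM in the arterial group to 20.3 in the venous group, and Col15a1 from 0.024 to 79.97.

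Ace, Edn1, Notch4 and Notch1 were higher at the arterial end. Ace, which makes angiotensin II, averaged 4055 ± 303 CPM in the arterial group and 1494 ± 300.3 in the venous group (log2 -1.46 ± 0.11, adjusted p = 0.00103), and Edn1, the vasoconstrictor endothelin, 258 and 92.9 CPM (-1.54, adjusted p = 0.0346). The receptors Notch4 (-1.03, adjusted p = 0.0196) and Notch1 (-0.98, adjusted p = 0.0309) fell towards the venous end, while the ligand Dll1 averaged 41.3 CPM at the arterial end and 165 at the venous end without passing the threshold (1.98, adjusted p = 0.0666). Klf2, Klf4 and Nos3, which respond to shear stress, did not pass, with log2 changes of -0.36, 0.26 and 0.18. The flow-responsive list had 11 of 17 members lower and 2 past the threshold (4 adjusted over the list alone, all lower), with adjusted p = 0.00419 by camera and adjusted p = 0.129 with an estimated correlation. The 2 past the threshold were Ace and Edn1. The list does not mark whether flow raises or lowers a member, so its direction gives no direction of a response to flow. The Notch list did not pass (adjusted p = 0.413, 2 of 11 members lower past the threshold, and 2 higher and 4 lower adjusted over the list alone), and its median and mean of 0.01 and 0.03 were positive while camera gave it as lower. Of 14 listed Notch genes 11 were tested. The arterial markers Dll4, Hey1 and Jag1, also of the Notch pathway, set the axis, so the list test does not cover them.

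Hypoxia and glycolysis genes, BMP and TGF-beta genes, and matrix genes fell towards the venous end. Of 19 hypoxia and glycolysis genes 17 were lower there, and Vegfa and the glycolytic regulator Pfkfb3 (-1.57; called in 4 of 19 alternatives) passed the threshold (10 adjusted over the list alone, all lower; camera adjusted p = 8.16e-12, and adjusted p = 0.00440 with an estimated correlation). Of 21 BMP and TGF-beta genes 17 were lower, with Smad6, an inhibitor of BMP signalling, at 566 ± 39.97 CPM in the arterial group and 93.0 ± 37.7 in the venous group (-2.66 ± 0.29, adjusted p = 0.00343). In that list 1 gene passed overall and 10 adjusted over the list alone, all lower (camera adjusted p = 4.67e-07, and adjusted p = 0.0122 with an estimated correlation). Of 22 basement membrane and elastic matrix genes 16 were lower. Eln and Col18a1 (-1.64 ± 0.17, adjusted p = 0.00311) fell and Col15a1 rose, with 11 lower and 2 higher adjusted over the list alone (camera adjusted p = 1.69e-06, and adjusted p = 0.0122 with an estimated correlation). The stromal collagen Col3a1 stood at 72.4 ± 126 CPM in the arterial group and 0.499 ± 0.771 in the venous group (adjusted p = 0.0943), and the mural markers Acta2 (102 ± 157 and 6.52 ± 7.88 CPM, adjusted p = 0.801) and Tagln (17.4 ± 11.6 and 4.13 ± 3.56 CPM, adjusted p = 0.591) were also higher on average at the arterial end. Without the 85 cells with a stromal marker the matrix list had adjusted p = 0.000182, and adjusted p = 0.0342 with an estimated correlation. These were the 3 lists of 12 called that held with an estimated correlation. They had no tested member in common, but each shared genes with other lists, such as Vegfa with the VEGF, angiopoietin and apelin list. Without the 85 cells the capillary, flow-responsive and pan-endothelial lists also held with an estimated correlation (adjusted p = 0.0133, 0.0342 and 0.0377).

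Genes of lipid handling moved in both directions. Lpl, the lipoprotein lipase, averaged 749 ± 155 CPM at the arterial end and 244 ± 64.4 at the venous end (-1.64 ± 0.21, adjusted p = 0.00754). Fabp4, a fatty acid carrier, went the other way, from 275 ± 47.1 to 827 ± 181 CPM (1.58 ± 0.18, adjusted p = 0.00423). Gpihbp1, which anchors Lpl to capillaries, was at 314 and 104 CPM without passing (-1.57, adjusted p = 0.0666). In the list of nutrient transport and lipid handling 16 of 24 members were lower, with 1 higher and 1 lower past the threshold (3 and 7 adjusted over the list alone; camera adjusted p = 0.0254, and adjusted p = 0.114 with an estimated correlation). The capillary list had 5 of 7 members lower, with Cd300lg past the threshold (-1.51, adjusted p = 0.0405) and 1 higher and 4 lower adjusted over the list alone, and gave adjusted p = 0.00328 by camera and adjusted p = 0.129 with an estimated correlation.

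None of the other lists held with an estimated correlation, and fry, another list test, called 8 lists on the axis, interferon, S phase and pan-endothelial among them (adjusted p = 0.0232, 0.0369 and 0.0244). The interferon and antigen presentation list was higher at the venous end (13 of 17 members), led by Ifitm3, an antiviral membrane protein, at 165 ± 8.73 and 374 ± 49.6 CPM (1.17 ± 0.17, adjusted p = 0.0181). That was its 1 gene past the threshold (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.114 with an estimated correlation). Higher at the venous end were also the proliferation list (8 of 9 members; adjusted p = 0.000179, and adjusted p = 0.235 with an estimated correlation), the S phase list (11 of 15; adjusted p = 0.0226, and adjusted p = 0.114 with an estimated correlation) and the immediate early list (13 of 16; adjusted p = 0.000178, and adjusted p = 0.129 with an estimated correlation). No member of the proliferation, S phase and immediate early lists passed by edgeR, and 3 immediate early genes, Egr1 and the near-identical copies Hspa1a and Hspa1b, whose separate counts are uncertain, did so adjusted over the list alone. Cells with at least 4 of 9 proliferation markers numbered 1, 2 and 5 in the arterial, middle and venous groups. Lower at the venous end were the pan-endothelial list (7 of 11; adjusted p = 0.00531, and adjusted p = 0.114 with an estimated correlation) and the trophoblast list (5 of 6; adjusted p = 0.00133, and adjusted p = 0.151 with an estimated correlation), whose member Prl3b1 averaged 88.1 ± 152 CPM in the arterial group and 0.549 ± 0.638 in the venous group. No member of either passed by edgeR, and 2 pan-endothelial genes and 1 trophoblast gene did so, all lower, adjusted over the list alone.

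Some of these calls were lost when 1 placenta was left out. Without placenta 1 the pan-endothelial and immediate early lists had adjusted p = 0.0630 and 0.0640, and without placenta 2 the nutrient and S phase lists had 0.0564 and 0.153. Without placenta 4 the proliferation, flow-responsive and S phase lists had 0.0878, 0.0712 and 0.0750, and without placenta 3 the S phase list had 0.0642. The tip cell (adjusted p = 0.767), erythroid (0.267), VEGF, angiopoietin and apelin (0.469), Wnt (0.160) and imprinted (0.167) lists were not called. The VEGF list had a median of 0.04 and a mean of -0.14 and was lower by camera. Of its 16 listed genes 11 were tested, without Nrp2 and Aplnr, which set the axis. Among its members Vegfa passed, and among Wnt genes the inhibitor Apcdd1 (-1.24, adjusted p = 0.0265), each the 1 gene of its list also when adjusted over the list alone. The imprinted list, at adjusted p = 0.0495 without placenta 3, held 2 genes past the threshold in opposite directions, which were also the genes past it adjusted over the list alone. Plagl1, a zinc finger regulator of growth, rose to the venous end (1.14 ± 0.15, adjusted p = 0.00953), and Igf2, the fetal growth factor, fell (-0.39 ± 0.06, adjusted p = 0.0254).

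**Figure D2:**
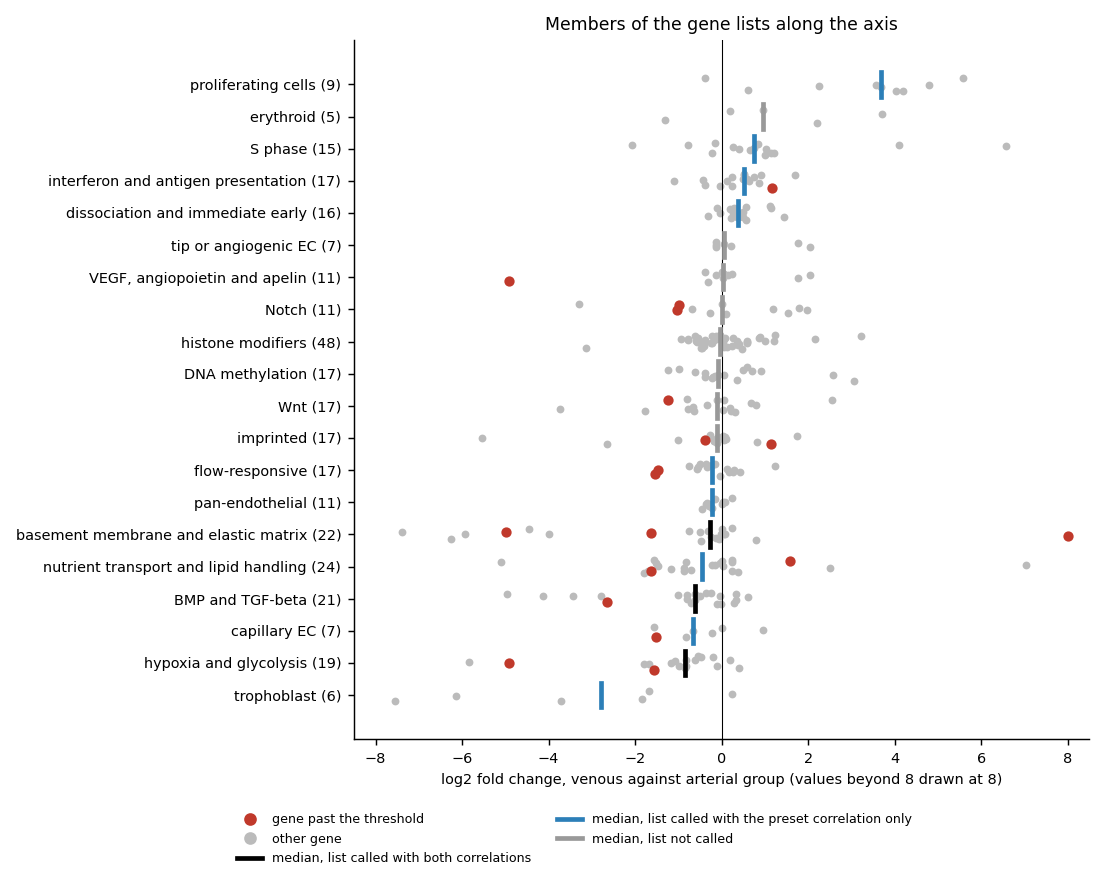
Log2 fold changes of the members of each gene list, venous against arterial group, with the number of tested members in brackets and values beyond 8 drawn at 8. Points are genes and vertical bars list medians; the hypoxia and glycolysis, BMP and TGF-beta, and matrix lists were called with both correlations.

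Enzymes of DNA methylation and histone modification were detected along the whole axis, and none passed the threshold. Dnmt3a, which adds new methyl groups, averaged 215 ± 61.4, 154 ± 56.0 and 185 ± 43.7 CPM in the arterial, middle and venous groups (log2 -0.23 ± 0.30, adjusted p = 0.929). Dnmt1, the maintenance enzyme, averaged 47.3 ± 24.5, 22.7 ± 16.3 and 33.9 ± 18.5 CPM (-0.61 ± 0.55, adjusted p = 0.865), and Tet3, which oxidises methylated cytosine, 286 ± 94.0, 205 ± 56.7 and 263 ± 52.4 CPM (-0.09 ± 0.28, adjusted p = 0.980). Dnmt3b (12.8 and 5.34 CPM at the arterial and venous ends), Uhrf1 (7.87 and 3.86), Tet1 (1.17 and 7.57) and Tet2 (35.6 and 48.8) had log2 changes of -1.24 ± 0.96, 0.59 ± 1.84, 3.07 ± 1.47 and 0.35 ± 0.74. For Uhrf1 the fitted change and the means had opposite signs, with 2 of 4 placentas in each direction. Among histone enzymes the smallest adjusted p belonged to the methyltransferase Ehmt2 at 79.7 and 159 CPM (0.87 ± 0.31, adjusted p = 0.369). By edgeR 0 of 17 DNA methylation genes and 0 of 48 histone genes passed, and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 0 and 5, DESeq2 called 0 of the 65 with 7 at that unadjusted p, and limma on mean CPM 0 with 6. The lists gave adjusted p = 0.730 and 0.979 by camera, with medians of -0.09 and -0.03 and means of 0.26 and 0.06 that differed in sign; camera gave the first as lower and the second as higher. In simulated sums 4% of genes changed by 1 on the log2 scale were recovered, so changes of that size were mostly not detectable in these sums of 4 placentas.

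**Figure D3:**
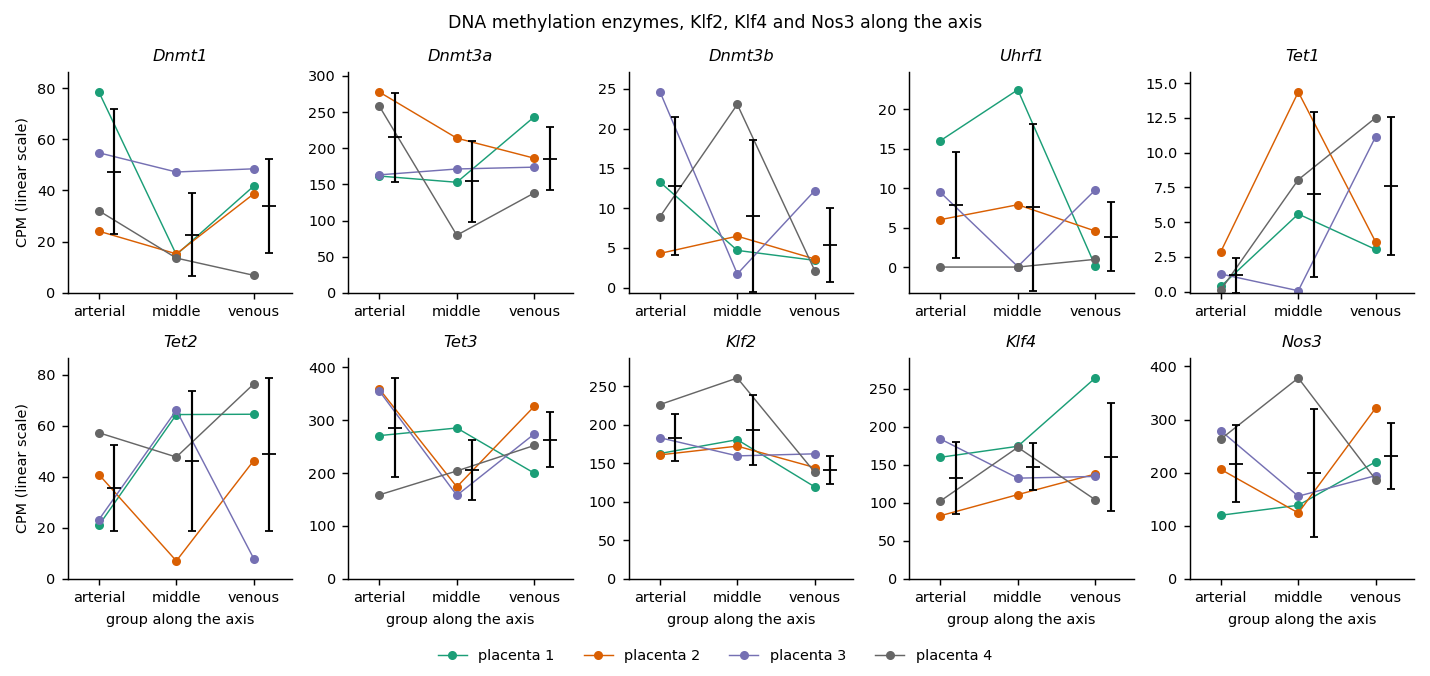
Levels of DNA methylation enzymes, Klf2, Klf4 and Nos3 in the arterial, middle and venous groups, in CPM on a linear axis. Points are the 4 placentas, and bars mark the mean and SD; Dnmt3a averaged 215, 154 and 185 CPM, and none of these genes passed the threshold.

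Clustering of all cells gave 3 clusters, and none could be named from the marker lists. Cluster 1 held 109 cells, 28.5 ± 3.36% per placenta (SD, n = 4), of which 47, 41 and 21 lay in the arterial, middle and venous groups. Fbln2, a fibulin of elastic matrix, averaged 892 ± 646 CPM there against 10.3 ± 13.3 in cluster 0 and 1.15 ± 0.417 in cluster 2 (log2 8.11 ± 0.70, adjusted p = 0.00208 by edgeR). Mgp, an inhibitor of vascular calcification, averaged 87.7 ± 98.6 CPM against 1.61 ± 2.85 and 0.195 ± 0.161 (7.27 ± 0.91, adjusted p = 0.0406). Eln (2030 ± 1756 CPM, adjusted p = 0.0681) and the arterial connexin Gja5 (1069 ± 759 CPM, adjusted p = 0.632) were among its 10 leading genes by fold without passing. Leading genes were ranked by mean CPM per cell, by which Eln stood at 1754 ± 1484 and Gja5 at 640 ± 437. By the same measure the arterial markers Gja4, Sema3g and Efnb2 were at 419, 1215 and 315 CPM in cluster 1, near the 418, 1189 and 377 of cluster 2. Over all cells, Fbln2 had a count in 15.1%, Mgp in 6.53%, Eln in 18.0% and Gja5 in 13.3%, so a small part of the cells carried them. These genes helped to form the clusters, so their differences describe the clusters and are not independent results.

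The arterial and matrix lists stood apart in cluster 1. Lists were tested on the values that formed cluster 1, so their p-values describe it and are not independent tests. All 12 arterial genes were higher there (camera adjusted p = 1.01e-09, and adjusted p = 0.0101 with an estimated correlation), as were 19 of 23 matrix genes (adjusted p = 6.92e-09, and adjusted p = 0.0206 with an estimated correlation). Of these, 0 arterial and 2 matrix genes passed the edgeR threshold, with 4 arterial genes higher, and 9 matrix genes higher and 1 lower, adjusted over the list alone. The flow-responsive (15 of 16 higher) and BMP and TGF-beta lists (18 of 21 higher) each gave adjusted p = 0.00101, and adjusted p = 0.124 with an estimated correlation, with 0 genes past the threshold and 1 each adjusted over the list alone. Col3a1, a stromal collagen, was also among the 10 leading genes of the cluster, at 75.6 ± 133 CPM against 0.370 in cluster 0 and 0 in cluster 2. Beside it stood Sfrp2, Serpinf1 and Htra1, secreted proteins also made by fibroblasts, at a mean per cell of 46.7, 40.3 and 59.2 CPM against 0.130, 0.664 and 2.59 in the others, named after their values were seen. The mural markers Acta2 (105 ± 157 CPM against 5.32 and 22.8) and Tagln (19.8 ± 10.2 against 3.60 and 5.37) were higher there on average, in 2 and 4 of 4 placentas. Without the 85 cells with a stromal marker, 26 of them in cluster 1, Fbln2 had a log2 change of 5.02 ± 1.14 (adjusted p = 0.841), Mgp and Lox had too few counts to be tested, and the arterial and matrix lists gave adjusted p = 0.0207 and 0.00549, and adjusted p = 0.447 and 0.452 with an estimated correlation. By edgeR 2 of 11595 genes passed, Fbln2 and Mgp, with 656 at an unadjusted p under 0.05, and DESeq2 called 170 and limma on mean CPM 12. The count was 1, 1, 1 and 3 without placenta 1, 2, 3 and 4, and Mgp was lost each time (adjusted p = 0.262, 0.604, 0.0667 and 0.0741).

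Clusters 0 and 2 differed in depth. Cluster 0 held 156 cells (40.7 ± 1.71%), had the highest median total of 663709 counts per cell, and had the trophoblast genes Ctsq and Krt8 among its 10 leading genes, at a mean per cell of 28.7 ± 57.3 and 21.8 ± 43.5 CPM (SD, n = 4). Placenta 2 alone carried both, at 115 and 87.0 CPM, and without it the means were 0.0222 and 0.0741. It held 32, 47 and 77 cells of the arterial, middle and venous groups, and cluster 2 held 49, 40 and 29. Cluster 2 held 118 cells (30.8 ± 2.15%) with a median total of 151561 counts and 2887 detected genes, against 605056 and 4434 in cluster 1. Its median share of mitochondrial counts was 0.0146% against 0.00463% and 0.00446% in clusters 0 and 1. Such counts were few in the whole matrix, with a median share of 0.00557% over all cells. By fold mt-Co3 ranked 10 among the genes of cluster 2, at a mean per cell of 39.7 CPM against 0.994 in the others. By edgeR 0 genes passed in cluster 0 or cluster 2, with 676 and 1293 at an unadjusted p under 0.05, while DESeq2 called 149 and 759 and limma on mean CPM 1 and 146. Scaling by library size alone moved the median log2 fold change of all genes in cluster 0 from 0.15 to 0.26.

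In cluster 0 the immediate early list was higher (15 of 16 members; camera adjusted p = 1.25e-08, and adjusted p = 0.0740 with an estimated correlation) and the arterial list lower (10 of 12; adjusted p = 1.25e-08, and adjusted p = 0.0182 with an estimated correlation). The pan-endothelial, capillary and flow-responsive lists were also lower and held with an estimated correlation (adjusted p = 0.0182, 0.0398 and 0.0398). All lists were tested on the values that formed the clusters, so their p-values in clusters 0 and 2 describe these and are not independent tests. Without the 85 cells with a stromal marker the arterial, pan-endothelial, capillary and flow-responsive lists had adjusted p = 0.0728, 0.0746, 0.0924 and 0.101 with an estimated correlation. Each was still called at the preset correlation (camera adjusted p = 1.40e-05, 0.000462, 0.000456 and 0.00100). Their median log2 changes went from -0.76, -0.16, -0.32 and -0.20 to -0.71, -0.08, -0.39 and -0.10. The Notch, BMP and TGF-beta, matrix and interferon lists were lower and the proliferation list higher at the preset correlation (adjusted p = 0.0654, 0.102, 0.0850, 0.182 and 0.335 with an estimated correlation). In cluster 2 the immediate early list was lower, 16 of 16 members, and the capillary, pan-endothelial and interferon lists higher (adjusted p = 2.30e-06, 0.0130, 0.0130 and 0.00979, and each adjusted p = 0.224 with an estimated correlation). The BMP and TGF-beta list in cluster 0 had 12 of 21 members higher, a median of 0.02 and a mean of 0.30, although camera gave it as lower. No member of these lists passed by edgeR in either cluster. Adjusted over the list alone, 2 arterial, 2 capillary, 2 pan-endothelial, 2 BMP and TGF-beta genes and 1 flow-responsive gene were lower in cluster 0, and 3 immediate early genes lower, 3 capillary and 2 pan-endothelial genes higher in cluster 2. Without placenta 2 the capillary, pan-endothelial and interferon lists in cluster 2 had adjusted p = 0.181, 0.0837 and 0.0837, and the BMP and interferon lists in cluster 0 had 0.0892 and 0.180. Without placenta 1 the pan-endothelial list in cluster 2 had 0.0528 and the proliferation list in cluster 0 had 0.0755, and without placenta 4 the proliferation and interferon lists in cluster 0 had 0.328 and 0.0606.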

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

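Values of 1 placenta lay far from the other 3 for 9 of 123 printed quantities scanned, where chance gives about 1 in 20, or 6.15. The scan first covered every named gene in all contrasts (26 of 419, with 20.9 by chance) and was narrowed to printed quantities after that count was seen. The summed CPM of trophoblast markers was 348 in placenta 2 against 29.1 to 51.1 in the others. The log2 difference between the venous and arterial groups of Cxcl12 was -9.09 in placenta 2 against -5.30 to -4.68. For the cell cycle genes Ube2c and Top2a it was 7.65 and 6.11 in placenta 4, against 0.35 to 1.34 and 0.48 to 0.87. Tpbpa, a trophoblast gene, stood at 0 in placenta 3 against -2.04 to -1.72, and Cd68, a macrophage gene, at -2.02 in placenta 4 against -0.05 to 0.20. The endothelial receptor Tie1 stood at -0.0685 in placenta 1 against 0.28 to 0.35, and Ifitm3 at 0.92 in placenta 1 against 1.24 to 1.26. The Y-linked Eif2s3y stood at -0.59 in placenta 3 against 0 to 0.11.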

How the results depend on the processing

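Along the axis 54 genes passed, and 44 to 63 did so under DESeq2 size factors, library size alone, no filter, no replicate block (63 genes, 44 of the 54 among them), the quality filter, the authors' gene range, no cycling cells, no cells with stromal markers (51, of which 38 among the 54), the odd-numbered markers and depth removed from the score. The count was 537 with the DESeq2 test, 116 with mean CPM per cell (55 higher and 61 lower at the venous end), 33 with cells of at least 200000 counts, 12 with 2 groups of equal size in place of 3, 32 with the axis from the even-numbered markers alone, and 8 to 29 with 1 placenta left out. The same total did not always mean the same genes. Of the 54, 54 were called again with DESeq2 size factors, 50 with the quality filter and 35 with depth removed from the score. With the odd-numbered markers 33 were, with the even-numbered 19, with 2 groups of equal size 10, and with cells of at least 200000 counts 28. Fewer cells or placentas entered where cells or placentas were left out, and for the other changes the cause was not tested. Leaving out cells of other types removed 0 cells and so tested nothing. Cluster 0 had 0 genes, but 149 with DESeq2 and 1 with mean CPM. Cluster 1 had 2, but 170 with DESeq2, 12 with mean CPM, 5 with no filter, 6 with no replicate block, 1 without cycling cells, 3 with cells of at least 200000 counts (Fbln2 kept, Mgp at adjusted p = 0.433), 0 without cells with stromal markers, 0 and 1 with clusters formed on one part of the genes, and 1 to 3 with 1 placenta left out. Cluster 2 had 0, but 759 with DESeq2 and 146 with mean CPM. Gene lists called fell from 12 to 3 on the axis, 10 to 4 in cluster 0, 4 to 2 in cluster 1 and 4 to 0 in cluster 2 with an estimated correlation. With fry they were 8 on the axis, 6 in cluster 0, 6 in cluster 1 and 1 in cluster 2, with no filter 6 in cluster 0, with mean CPM 5 and 2, and as few as 1 in cluster 2 with 1 placenta left out or without cells with stromal markers. Without the latter cells Eln, Edn1 and Pfkfb3 lost their calls on the axis (edgeR adjusted p = 0.864, 0.0689 and 0.286) and Dll1 and Slc6a6 gained them (0.0451 and 0.0103). Eln kept 26.9% of its log2 change there, but Edn1 kept 100% and Pfkfb3 85.8%. Among lists, the nutrient list on the axis (0.1004), the proliferation, Notch, matrix and interferon lists in cluster 0 (0.0525, 0.221, 0.0525 and 0.0719) and the capillary, pan-endothelial and interferon lists in cluster 2 (0.604, 0.463 and 0.244) were then not called, while the VEGF and imprinted lists on the axis (0.0490 each), the S phase list in cluster 0 (0.00195) and the capillary list in cluster 1 (0.0358) were. With an estimated correlation the 4 lists of cluster 0 and both of cluster 1 were then lost, and the capillary, flow-responsive and pan-endothelial lists on the axis gained. At the preset correlation these lists of clusters 0 and 1 were all still called. Cells with at least 3 markers at 10 CPM were 1.57% for erythroid and 1.83% for stroma, against 0%. Cells with any Y-linked gene fell from 67.7, 88.4, 92.7 and 40.6% in placentas 1 to 4 to 26.0, 76.8, 68.8 and 16.7% when 10 CPM was required. In placentas 1 and 4 these cells carried only Kdm5d or Uty, whose assignment is uncertain, as Ddx3y and Eif2s3y were found in 0 cells there. For enzymes the count stayed at 0, and the mean shares of clusters moved by less than the spread between placentas. Within placenta 4 the quality filter moved more, with cluster 2 going from 31.25 to 26.67% and cluster 0 from 42.71 to 45.56%. Of 1959 values for single named genes on the axis, 1779 kept their side of the threshold, 135 lost it and 45 gained it, with no change of direction past it. Of 19 alternatives on the axis Pfkfb3 kept its call in 4, Cd300lg and Edn1 in 9, and Eln, Notch1, Apcdd1 and Ifitm3 in 10; Pfkfb3 lost it under library size alone, the quality filter, no cycling cells, mean CPM and each placenta left out, among others. The smallest depth, in placenta 4, and the 4% of simulated changes of 1 on the log2 scale recovered limit what the 0 counts can say.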

Other observations

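The tests of stromal or mural reads and cells and of other cell types in cluster 2 were chosen after the results were seen. Imprinted transcripts were abundant in these cells. Igf2 averaged 34092 ± 305 CPM over all cells (SD, n = 4), Cdkn1c, a cell cycle inhibitor, 9181 ± 908, and Dlk1, a Notch ligand relative, 5854 ± 1022. Along the axis Igf2 was higher at the arterial end, while Plagl1 and Magel2 were higher at the venous end; Magel2 averaged 512 ± 119 and 1789 ± 369 CPM (3.48-fold, adjusted p = 0.00343). Lyve1 and Stab2, scavenger receptors of sinusoidal or lymphatic type, moved in opposite directions. Lyve1 averaged 1235 ± 251 CPM in the arterial and 189 ± 85.3 in the venous group (-2.75 ± 0.42, adjusted p = 0.0196), while Stab2 went from 268 ± 125 to 879 ± 29.2 CPM (1.78 ± 0.27, adjusted p = 0.0196). Magel2, Lyve1 and Stab2 were chosen after their values were seen.

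The authors' own table held 3 clusters of 154, 119 and 91 cells, with median pseudotime scores of 9.38, 3.42 and 0.00621. The median total counts of these clusters were 648571, 644348 and 148624, so the cluster with the lowest median pseudotime was also the one with the fewest counts.

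In edgeR's fit 54 genes passed along the arteriovenous axis. As many were found in 1 of 100 regroupings of the groups inside each placenta, the real one included, with at most 2 genes in any other. That is the least that 100 regroupings can give, and it argues against chance labels of these sums. The cells of each sum were already sorted by the score, so the regroupings do not test how that sorting arose. As many were found in 0 of 100 axes built from random gene lists of the same size, with at most 3. Genes drawn at random need not vary together as markers do, so other sets of genes that vary together were not tested. After the trend of the score with depth was removed 64.8% of the genes were called again with the same direction, and without cycling cells 83.3% were, which argues against depth or cycling cells as the whole cause. Cells with stromal or mural transcripts were tested by leaving out the 85 cells in which such a marker reached 10 CPM. The 54 genes kept a median of 104% of their log2 change (quartiles 96.3 and 110%), which argues against these cells as the source, except for Eln, which kept 26.9%. Of 12 arterial markers held out in turn from the axis all were higher at the arterial end and 4 passed. Of 10 venous markers held out 6 were higher at the venous end and 1 passed. Some venous markers ran the other way or hardly moved between the groups they helped to set. Vwf averaged 1361 ± 844 CPM in the arterial and 796 ± 747 in the venous group (SD, n = 4). Tmem100 stood at 2013 ± 417 and 1538 ± 125, and Flrt2 at 467 ± 150 and 448 ± 93.1. Bgn was near level, at 556 ± 299 and 576 ± 91.2. The means of Nr2f2, Ephb4, Nrp2, Aplnr, Emcn and Slco2a1 were higher in the venous group. Only part of the venous list therefore marks the venous end. A zonation of vessels remains a hypothesis, and the position of the cells in the tissue was not measured.

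Large-vessel matrix genes were high in cluster 1, and a candidate explanation is reads from stromal or mural cells. Of 11 pericyte and stroma markers 2 were higher in cluster 1 in at least 3 placentas by mean CPM per cell, Col3a1 and Tagln. Only 4 of the 11 reached 10 CPM in any cluster, a check added after the results were seen, so the levels of the markers cannot decide. By the same measure Col1a1 was at 0.0126 CPM in cluster 1 against 4.55 and 0.249, and Pdgfrb at 1.77 against 14.4 and 2.96. When cells with such a marker at 10 CPM were left out, the 9 matrix genes higher in cluster 1 kept a median of 39.0% of their log2 change with Mgp and Lox, no longer testable, counted as lost, and 61.8% over the 7 still tested. With as many cells left out at random, a control added after the first value was seen, these medians were 58.5 to 115% and 60.8 to 115% in 40 draws. As low a median was reached in 0 of 40 draws with the lost genes counted and in 1 of 40 over the genes still tested. By the values set for either outcome the verdict still depends on the untestable genes, and the source of the matrix genes as a set stays open. Lama3 kept 100.4%, Ltbp4 97.9%, Col18a1 78.6%, Fbln2 61.8%, Fn1 39.0%, Eln 32.1% and Fbln5 14.9%; Eln and Fbln2 lay below all 40 draws, whose lowest values were 58.5 and 78.2%. Whether the cluster exists only because the same genes formed it was tested with clusters formed on one part of the genes. The 9 matrix genes, held out, had a median log2 change of 5.18 (0.64 to 7.17), each more than 2 SE above 0. They were picked as higher in cluster 1 of these same cells. The most arterial of the new clusters held 73.4 and 48.6% of cluster 1. High values of the 9 genes were therefore likely in advance, so they cannot decide this. The whole list of 23 had a median of 0.18, between the values set for either outcome, with basement membrane genes near 0. The test was moved to the 9 genes after that was seen. As many genes as the 2 of cluster 1 were found in 1 of 81 ways of picking a cluster sum per placenta, with at most 0 in the others. The clusters were formed on the values tested, so this comparison says nothing about chance.

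Cluster 2 had the fewest counts, and the number of reads per cell could set it apart. Thinning to 100000 reads left 324 cells, and 73 of the 118 of cluster 2, so its cells of lowest depth were not tested. Then 2 clusters formed (adjusted Rand index 0.158 to the original ones). Of the 73 cells 61.6% fell in 1 cluster, of which they made up 34.9%; this lies between the values set for either outcome, so depth and cell state cannot be told apart here. At these equal reads its cells had a median of 2879 detected genes against 4059 in the others, and fewer in each of the 4 placentas, so the number of reads alone does not explain its fewer detected genes; less RNA or RNA of lower quality was not tested and stays open. In 0% of its cells did a list of another cell type exceed the endothelial list, which argues against another cell type. For clusters 0 and 2, with 0 genes past the threshold, 81 of 81 ways of picking a cluster sum per placenta gave as many, with at most 2 genes. A count of 0 is reached by every such pick, so this comparison says nothing about chance.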
